A study of Mus musculus with 6 samples.

How the data were processed

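Messenger and other RNA of sorted long-term haematopoietic stem cells (HSCs) from mouse bone marrow was measured by bulk RNA-seq. Per the labels' protocols, RNA was isolated with a column kit from cells sorted by flow cytometry for low or high Asrij, ribosomal RNA was depleted, and libraries were built with a directional (stranded) kit. The molecule field of the labels names polyA RNA, whereas the protocol describes ribosomal RNA depletion, and the labels do not settle which was used. If it was depletion, transcripts without a polyA tail, such as replication-dependent histones, can be counted here. The deposited table holds whole-number read counts per gene symbol, not normalized, for the 6 libraries. Per the submitters' processing notes, FastQC, HISAT2, SAMtools and Subread were used with the mm10 mouse genome, and their versions, the annotation and the counting options are not given in the sources used here. Each column was tied to its sample through the library name in the labels.

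The strand setting and the treatment of multiply mapped reads are not given in the sources used here, and the counts carry traces of shared reads. The ratio of Rn7s1 to Rn7s2 lay between 0.998 and 0.999 in the 6 libraries, that of ATP6 to its nuclear copy Gm10925 was 1.01, and that of Hba-a1 to Hba-a2 lay between 1.04 and 1.08. The overlapping genes Asb17 and Asb17os had count ratios between 0.945 and 1.02 in the libraries with counts. Values of near-identical or overlapping genes are therefore uncertain as values of a single gene.

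The counts were analysed with R 4.3.3. The main test was the quasi-likelihood test of edgeR 4.0.16 with TMM factors, robust dispersion shrinkage and group as the only term, on genes kept by filterByExpr with its default settings (minimum count 10, minimum total count 15), which left 21445 of 49997 genes. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. A fold change is Asrij high over Asrij low, levels are CPM, counts scaled to a common library total, computed from the deposited counts with TMM factors, and standard errors (SE) of log2 fold changes were derived from the quasi-likelihood statistic. For genes with no count in a group, fold changes were computed against a floor of 3 counts over the group, and such bounds cover counting error only.

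Before the data were examined, 48 gene lists were fixed, covering stem cell states, cell cycle, signalling, metabolism, RNA and protein synthesis, and markers of other cell types. Older symbols were matched through RefSeq synonyms (GRCm38.p6, the assembly behind mm10), and mitochondrially encoded genes through their RefSeq names, so that 1486 of 1488 written symbols were found. Some lists hold the older and the newer symbol of a gene, which was then counted once, and lists share members. Lists were tested with limma 3.58.1 camera with a preset correlation of 0.01 between genes on log2 CPM (prior count 2), adjusted over the 48 lists, beside camera with an estimated correlation, with which 0 of the 48 lists were called, and fry. With an estimated correlation camera takes its degrees of freedom from the 6 libraries and not from the genes, so small p-values are hard to reach. Fry's p-value tests whether a list's genes move, on balance, one way, and does not compare the list with other genes.

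Named genes followed a rule fixed before the data were examined. It takes Ociad1 and Ociad2. It takes the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, leaving out unnamed gene models and pseudogenes. It takes up to 4 members of each list with the smallest p past the threshold. Hlf, Mecom, Fgd5, Klf1, Mpo, Mmp9, S100a8, S100a9, Hba-a1, Hba-a2, Hbb-bs, Hbb-bt, Alas2, H1f0, ND3 and ND6 were named after their values were seen. So were members that moved against their list or stood out in it (Ccnd2, Trp53bp1, Xrcc4, Gfi1, Rb1, Ptpn11, Pink1, Sqstm1, Mycn, Trib3, Zbtb46, Ly6c2, Sod3, Gpx3, Cat, Pparg, Aldh1a1, Itgb1, Itga5, Cd44, Adam17, Psenen, Dtx4, Rfng, Ighm, Igkc, Igfbp5 and Lat). Results of some genes that the rule or a list takes in are not reported here. Coordinates are those of RefSeq on GRCm38.p6.

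Library totals ran from 24707012 to 72855125 counts, so a gene with no count in the smallest library was below 3 in 24707012 counts, and the depth of the Asrij low libraries limits low genes most. The labels do not say whether the 3 libraries of a group came from separate mice, so p-values measure the spread between these samples, which may be technical. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom from 75.3 to 168). The pipeline was tested on simulated counts drawn from the means, dispersions and library sizes of this comparison, with 200 changed genes. Of the changed genes left by the filter among 20724 tested, 10 of 96 changed 2-fold were recovered (10.4%) and 49 of 92 changed 4-fold (53.3%). Of the calls, 1.67% (1 gene) were unchanged genes. With 200 changed genes the adjusted threshold is stricter than with the 8452 genes called in the data. These shares therefore do not carry over to the comparison itself. When the complex I list alone was raised 2-fold, it was called and 0 of the other lists were. The simulated genes varied independently, whereas the estimated correlation of the complex I list in the data was 0.46. The simulation therefore does not show how often lists are called falsely here.

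Alternatives covered 3 other scalings, DESeq2 1.42.0, limma-voom with and without sample quality weights, 2 other count filters, removal of mitochondrially encoded, ribosomal RNA and globin genes, each library left out in turn, the replicate number as a block, other thresholds, other list tests and another prior count. A trend on transcript length and GC content was fitted with mgcv 1.9.3 on GENCODE vM21 transcripts. No sample was left out of the main analysis.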

Results

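Asrij is the protein encoded by Ociad1, an OCIA domain protein found on endosomes and mitochondria. Long-term HSCs, the bone marrow cells that sustain blood formation, were sorted from 4-month-old C57BL/6J mice into a population with low and a population with high Asrij, and each was profiled by bulk RNA-seq in 3 libraries. The comparison asks how gene expression differs between stem cells with low and high Asrij. The Asrij low libraries held 46240743, 26878007 and 24707012 counts (replicates 1 to 3), and the Asrij high libraries held 62732782, 66227020 and 72855125, so the Asrij high libraries were deeper. Unless stated otherwise, levels are CPM as mean ± SD with n = 3 per group, and adjusted p-values are from edgeR's quasi-likelihood test over 21445 genes.

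Ociad1 itself (chromosome 5, 73292769 to 73314077) was higher in Asrij high, at 80.3 ± 5.76 CPM against 51.6 ± 5.72 CPM, a log2 fold change of 0.64 ± 0.16 (SE, adjusted p = 0.0115). All 3 Asrij high libraries lay above all 3 Asrij low libraries. The difference amounted to 1.55-fold. The labels do not state whether a reporter or an antibody was read in the sort or how pure the gates were, and under genotype they give the strain. It did not pass the threshold with library totals as the only scaling (log2 0.36, adjusted p = 0.133), with upper quartile factors (log2 0.36, adjusted p = 0.0834) or without Asrij high replicate 1 (log2 0.53, adjusted p = 0.0831), and over all alternatives the adjusted p ran from 0.00559 to 0.133. The paralogue Ociad2, which lies near Ociad1 on chromosome 5 (73322198 to 73338947), had 5.90 ± 0.960 CPM in Asrij high and 6.72 ± 1.41 CPM in Asrij low, a difference that did not pass the test (log2 -0.19 ± 0.32, adjusted p = 0.67).

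Libraries grouped by Asrij level. The first principal component held 57.7% of the variance and separated the groups, and the second (20.6%) spread the Asrij low libraries. Spearman correlations were 0.976 to 0.983 within Asrij high, 0.941 to 0.962 within Asrij low and 0.863 to 0.928 between groups. Asrij high replicate 2 lay nearest to the Asrij low libraries on the first component (70.2, against 137 and 112), and on the second Asrij low replicates 2 (113) and 3 (-108) lay farthest apart. In Asrij low replicate 3 the 10 most abundant genes took 19.4% of counts, against 9.68% and 9.99% in replicates 1 and 2 and 5.15% to 7.46% in Asrij high.

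**Figure D1:**
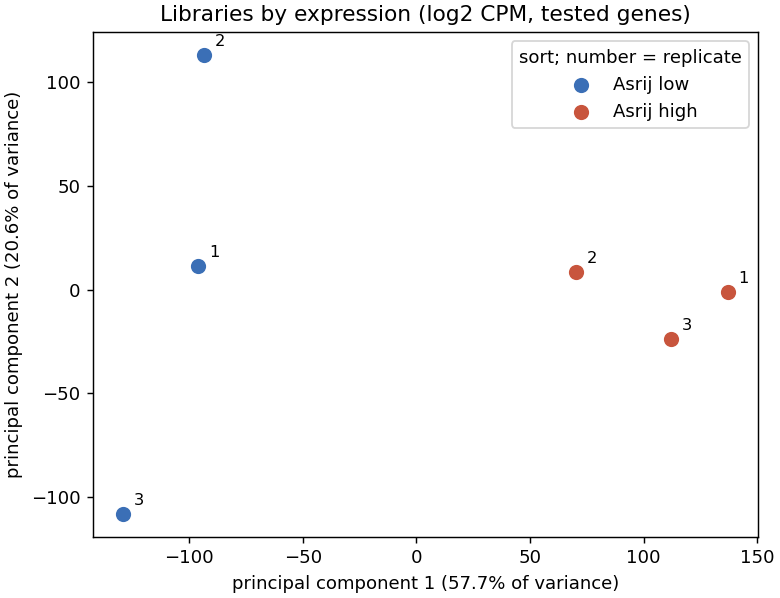
Principal components of log2 CPM of the tested genes, with 57.7% of the variance on the x axis and 20.6% on the y axis, and a point per library, coloured by sort and numbered by replicate. The Asrij low libraries lie at negative and the Asrij high libraries at positive values of the first component.

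Stem cell identity genes were lower and cell cycle and ribosome biogenesis genes were higher in Asrij high with camera at its preset correlation, within a broad difference between the populations. With an estimated correlation none of these lists was past the threshold (adjusted p = 0.349 for HSC identity and 0.33 for the cell cycle and ribosome biogenesis lists). Of 21445 genes, 8452 (39.4%) changed, 4655 higher and 3797 lower in Asrij high, and 6126 changed at least 2-fold, 2982 higher and 3144 lower. Groups did not overlap for 55% of tested genes, where chance gives 10% with 3 against 3. The count fell to 5481 without Asrij high replicate 1. Scaling by library totals moved the median log2 fold change of all genes by -0.27 and gave 3270 higher and 4856 lower genes, 40.2% higher in place of 55.1%, and upper quartile factors moved it by -0.27 and gave 39.9%. Fold changes below are therefore relative to TMM scaling.

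Among named genes, the largest rises were in genes without any count in the Asrij low libraries. Mc1r, the melanocortin 1 receptor (chromosome 8, 123407082 to 123410744), had 3.28 ± 1.34 CPM in Asrij high, at least 116-fold higher than the floor of 3 counts over the Asrij low group, and the peroxisomal gene Acnat1 (chromosome 4, 49443532 to 49481315) was at least 115-fold higher. Tex21 was at least 88.5-fold and Aknad1 at least 76.1-fold higher. Asb17 and Asb17os, which overlap on chromosome 3 and share counts, were at least 190-fold and at least 194-fold higher. Of the genes present in both groups, the metallothionein Mt2 rose from 0.612 ± 0.736 to 44.1 ± 16.1 CPM (log2 6.23 ± 0.95, adjusted p = 0.00223) and the sphingosine kinase Sphk1 from 6.88 ± 4.23 to 329 ± 62.7 CPM (log2 5.59 ± 0.45, adjusted p = 2.04e-04). Tlcd4 (log2 5.69 ± 0.31), the acyl-CoA synthetase Acsl6 (5.54 ± 0.42), the epoxide hydrolase Ephx2 (6.08 ± 1.01) and the desaturase Scd3 (5.97 ± 1.38) rose as well. Ephx2 and Scd3 had no count in Asrij low replicates 2 and 3, so their fold changes rest on replicate 1. Without it the fitted values were 12.44 and 10.24, which are no bounds. In Asrij high, Scd3 had 0.251 CPM in replicate 2 against 3.53 and 5.63 CPM in replicates 1 and 3, and in Asrij low replicate 1 it had 0.111 CPM. Its log2 fold change was 5.29 without Asrij high replicate 3, and it was not past the threshold in limma-voom (adjusted p = 0.146, range over alternatives 9.52e-06 to 0.146). Without Asrij low replicate 3 the log2 fold change of Mt2 was 7.45.

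The largest falls among named genes ran from -4.90 to -10.78. Ighd, the heavy chain of IgD, had 0.166 ± 0.0329 CPM in Asrij high and was lower there (log2 -5.37 ± 0.46, adjusted p = 2.04e-04). The chemokine Cxcl14 had 16.7 ± 10.7 CPM in Asrij low and 0.531 ± 0.115 CPM in Asrij high (log2 -4.96 ± 0.54). Slamf7 (-5.16), Zfhx4 (-5.85), Svep1 (-5.12), Igfbp3 (-5.10) and Ebf3 (-4.90) were lower too. The collagen gene Col3a1 (-5.31), Serpina3n (-5.73), Serping1 (-4.95) and the immunoglobulin gene Ighg2c (-10.78) fell as well. Without Asrij high replicate 1 they were at -5.50, -5.49, -4.91 and -10.94, but their calls were lost (adjusted p = 0.0853, 0.0579, 0.0521 and 0.222). Over alternatives their adjusted p ran from 3.55e-06 to 0.0853, from 7.30e-07 to 0.0599, from 1.31e-11 to 0.0521 and from 2.75e-04 to 0.391. Ighg2c had 183 CPM in Asrij low replicate 3 against 0.370 and 2.67 CPM in replicates 1 and 2. It was not past the threshold without Asrij high replicate 2 or 3 either (-10.17 and -11.70, adjusted p = 0.166 and 0.197). Ebf3 lost its call with Asrij low replicate 3 and Asrij high replicate 2 both left out (adjusted p = 0.0544, range over alternatives 1.43e-07 to 0.0544). Without Asrij low replicate 3 the falls were smaller, at -5.42 for Ighg2c, -3.54 for Svep1 and Serping1, -3.77 for Igfbp3, -3.64 for Ebf3, -4.14 for Col3a1, -4.93 for Serpina3n, -5.08 for Zfhx4 and -4.38 for Cxcl14. Without Asrij high replicate 3, Col3a1 was at -6.16, Serpina3n at -7.73 and Zfhx4 at -6.50, without replicate 2 they were at -4.69, -5.12 and -5.23, and without replicate 1 Ebf3 was at -5.92.

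HSC identity genes were lower in Asrij high as a group. Of 35 tested members, 29 fell and 1 rose (29 and 1 adjusted over the list alone), with a median log2 fold change of -1.97 (camera adjusted p = 1.40e-08; adjusted p = 0.349 with an estimated correlation). Procr, which encodes the endothelial protein C receptor used to sort HSCs, had 34.3 ± 3.75 CPM in Asrij low and 4.06 ± 2.46 CPM in Asrij high (log2 -3.08 ± 0.45, adjusted p = 0.00115). The transcription factor genes Erg (log2 -2.04 ± 0.27) and Prdm16 (-2.32 ± 0.33) fell, and so did Hlf (-2.62), Mecom (-2.32) and Fgd5 (-2.74). Mecom and Fgd5 were not past the threshold without a count filter (adjusted p = 0.0844 and 0.0791, ranges over alternatives 1.55e-06 to 0.0844 and 4.59e-07 to 0.0791). Gfi1b, a repressor needed in erythroid and megakaryocytic cells, was the member that rose (1.54 ± 0.22, adjusted p = 0.00106). The list median was -2.68 with Asrij low replicate 3 and Asrij high replicate 2 both left out. Within Asrij high, Hlf was at 86.4 CPM in replicate 2 against 18.1 and 49.9 CPM in replicates 1 and 3.

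Quiescence genes followed in part. Among 28 members, 15 fell and 3 rose (18 and 3 adjusted over the list alone), with a median of -0.78 (camera adjusted p = 5.65e-04; adjusted p = 0.349 with an estimated correlation). Of these members, 14 also stand in another list. Klf2 is in the immediate early and dissociation list (median -1.76) and Tgfbr2 in the TGF-beta and BMP list (median -1.06). The fall of this list therefore need not be particular to quiescence. The cyclin-dependent kinase inhibitor gene Cdkn1c fell from 16.8 ± 1.10 to 2.21 ± 0.900 CPM (log2 -2.92 ± 0.35, adjusted p = 4.75e-04), with Tgfbr2 (-2.13) and Klf2 (-3.41), whereas the inhibitor gene Cdkn2c rose (2.02 ± 0.28) with Gfi1 (1.22) and Rb1 (1.01). Rb1 was not past the threshold without Asrij low replicate 1 or Asrij high replicate 1 or 3 (adjusted p = 0.0504, 0.0632 and 0.0821, range over alternatives 9.85e-04 to 0.0821). In the list of genes reported to change in HSCs with age, 11 of 32 fell and 3 rose, both also adjusted over the list alone (median -0.87, camera adjusted p = 0.00716; adjusted p = 0.484 with an estimated correlation). Alcam (-1.40) and Slamf1 (-2.38) fell and Mt1 (3.97), Mt2 and Aldh1a1 (0.86) rose. Without Asrij high replicate 2, Slamf1 was at -3.09. The list was not called without Asrij low replicate 3 (adjusted p = 0.053, range over alternatives 0.00111 to 0.484). Homing, adhesion and niche receptor genes had 11 falls and 5 rises among 26 (13 and 6 adjusted over the list alone), with the integrin gene Itgb7 (-1.81) lower and Epor (2.15) and Cd82 (1.38) higher. The largest fall in the list was that of Cxcl12 (-4.30), a stromal chemokine gene that is also in the mesenchymal list (median -3.60), and its call was lost without Asrij high replicate 1 (adjusted p = 0.0758, range over alternatives 4.52e-06 to 0.0758). It was at -3.21 without Asrij low replicate 3. The other rises were those of Itgb1 (0.75), Itga5 (0.70) and Cd44 (0.51). Itgb1 was not past the threshold without Asrij low replicate 1 or Asrij high replicate 1 or 3 (adjusted p = 0.0581, 0.0508 and 0.0597). Itga5 was not without Asrij low replicate 2 or 3 or Asrij high replicate 1 or 2 (0.0563, 0.0968, 0.114 and 0.053). Cd44 was past it only without Asrij high replicate 2 among fits with 1 library left out, and otherwise at 0.0659, 0.0528 and 0.096 without Asrij low replicates 1 to 3 and 0.172 and 0.183 without Asrij high replicates 1 and 3. Over alternatives these 3 genes reached 0.0651, 0.203 and 0.289, under library totals. The list call was near the threshold (median -0.94, camera adjusted p = 0.0425; adjusted p = 0.33 with an estimated correlation). It was lost without Asrij low replicate 1 (adjusted p = 0.0522) or 3 (0.102) or Asrij high replicate 1 (0.054) or 2 (0.0869), with adjusted p from 0.019 to 0.33 over all alternatives.

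Cell cycle genes were higher in Asrij high. In the G1/S and DNA replication list, 36 of 41 members rose and 1 fell, both also adjusted over the list alone (median 1.97, camera adjusted p = 2.10e-12), and in the G2/M and mitosis list 39 of 40 rose and 0 fell, also adjusted over the list alone (median 2.83, camera adjusted p = 5.64e-17). Both lists had an adjusted p = 0.33 with an estimated correlation. The replication initiation factor gene Mcm10 had 12.7 CPM in Asrij low and 128 ± 27.1 CPM in Asrij high (log2 3.34 ± 0.22, adjusted p = 1.32e-04), and the loading factor gene Cdc6 rose by 3.22 ± 0.28. The member that fell was the cyclin gene Ccnd2 (-0.82, adjusted p = 0.0363), which was not past the threshold without Asrij low replicate 1 or 2 or Asrij high replicate 1 or 3 (adjusted p = 0.125, 0.116, 0.0746 and 0.0819, range over alternatives 0.00126 to 0.125). Cdc20, an activator of the anaphase-promoting complex, rose from 31.3 ± 4.14 to 250 ± 40.4 CPM (adjusted p = 1.32e-04), and the cyclin gene Ccnb1 and the kinetochore gene Nuf2 each rose by 3.62. Of 50 histone genes in the list of replication-dependent histones, 49 rose and 1 fell, both also adjusted over the list alone (median 2.49, camera adjusted p = 1.50e-17; adjusted p = 0.33 with an estimated correlation). H4c4 rose by 1.86 ± 0.16 and H2bc3 by 2.80 ± 0.21. The member that fell was H1f0 (-0.94, adjusted p = 0.0446), a linker histone that is not replication-dependent. This call was lost without Asrij low replicate 1 or 2 or Asrij high replicate 1 or 3 (adjusted p = 0.147, 0.15, 0.118 and 0.105, range over alternatives 0.00139 to 0.15).

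DNA repair genes rose in 25 of 37 cases and fell in 2 (27 and 2 adjusted over the list alone), with a median of 1.03 (camera adjusted p = 4.62e-07; adjusted p = 0.33 with an estimated correlation). Fancd2 (3.06), Fanci (2.10), Brca1 (2.45) and Brca2 (1.71) were among them. The falls were those of Trp53bp1 (-0.69) and Xrcc4 (-1.12, adjusted p = 0.0371). Xrcc4 was not past the threshold without Asrij low replicate 1 or 2 (adjusted p = 0.0996 and 0.0584) or without Asrij high replicate 1, 2 or 3 (0.1, 0.109 and 0.0661), with a range over alternatives of 0.0074 to 0.109. Of 10 subunits of the COP9 signalosome, a complex that removes Nedd8 from cullins, 8 rose and 0 fell, also adjusted over the list alone (median 1.14, camera adjusted p = 0.00184; adjusted p = 0.383 with an estimated correlation). Cops5, its catalytic subunit gene, was at 71.4 ± 11.6 CPM against 25.9 ± 6.37 CPM (log2 1.46 ± 0.23, adjusted p = 0.00136). The p53 targets went both ways, with 6 rises and 11 falls among 30, also adjusted over the list alone, and were not called as a list (median -0.61, camera adjusted p = 0.105). Bax (1.26) and Aen rose while Trp53inp1 (-2.13) and Btg2 (-1.60) fell.

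**Figure D2:**
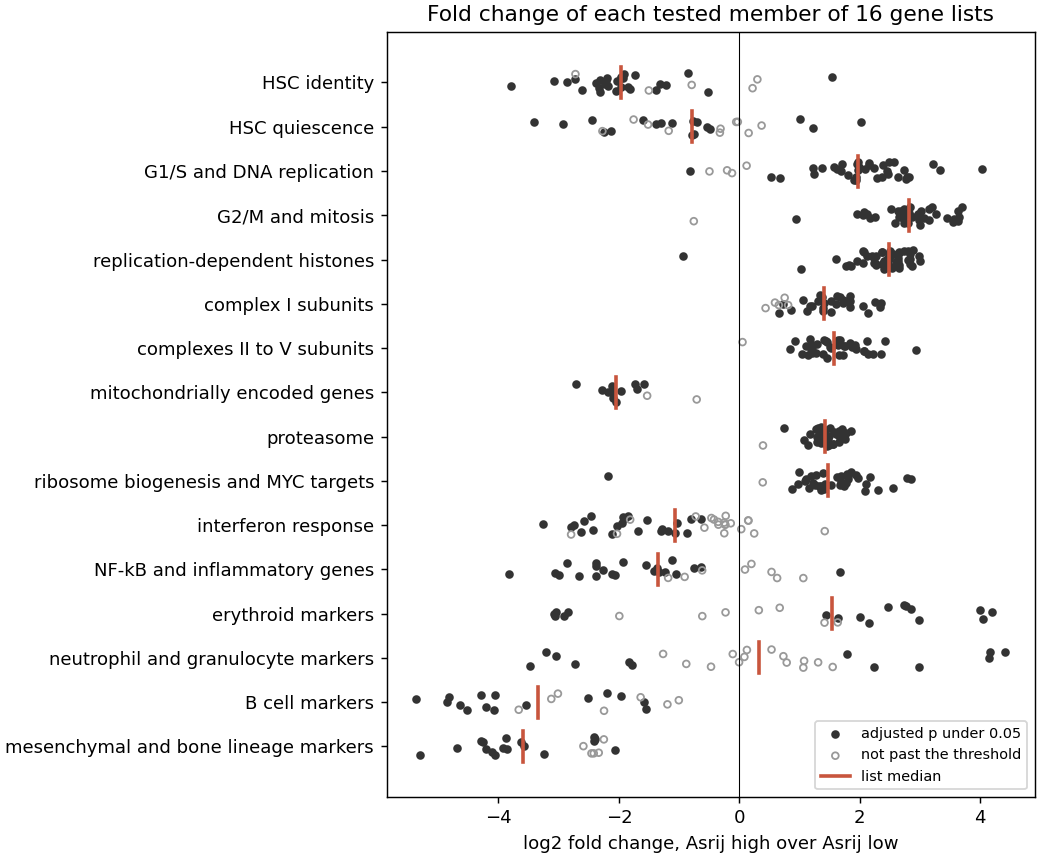
Log2 fold change of each tested member of selected gene lists, Asrij high over Asrij low, on the x axis, with a list per line; filled points passed an adjusted p of 0.05, open points did not, and the vertical bar is the list median. The medians of HSC identity (-1.97) and B cell markers (-3.34) lie below 0 and those of G2/M genes (2.83) and complex I subunits (1.40) above it.

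Nuclear genes of mitochondrial energy metabolism were higher in Asrij high. Among 37 genes in the list of nuclear complex I subunits, 32 rose and 0 fell (36 and 0 adjusted over the list alone; median 1.40, camera adjusted p = 4.97e-11; adjusted p = 0.33 with an estimated correlation). In the list of complexes II to V, which also holds the cytochrome c gene Cycs, 39 of 40 genes rose and 0 fell, also adjusted over the list alone (median 1.58, camera adjusted p = 5.86e-14). Of 23 tricarboxylic acid cycle genes 22 rose and 0 fell, also adjusted over the list alone (median 1.25, camera adjusted p = 4.61e-08). The latter 2 lists also had an adjusted p = 0.33 with an estimated correlation. Ndufa1 rose from 8.24 ± 2.09 to 41.8 ± 8.60 CPM (log2 2.35 ± 0.27, adjusted p = 3.98e-04), Cox7c by 2.12, Sdhd, which belongs to complex II and the cycle, by 2.13, and the citrate synthase gene Cs by 1.56. Genes of mitochondrial dynamics and mitophagy had 21 rises and 3 falls among 34 (23 and 4 adjusted over the list alone; median 0.65, camera adjusted p = 0.00353; adjusted p = 0.349 with an estimated correlation), including the import pore gene Tomm40 (1.94) and the prohibitin gene Phb2 (1.82). Among the falls were those of the mitophagy genes Pink1 (-1.31) and Sqstm1 (-0.54). Sqstm1 was not past the threshold without Asrij low replicate 1 or 2 (adjusted p = 0.104 and 0.0974) or Asrij high replicate 1, 2 or 3 (0.0614, 0.0629 and 0.0674), with a range over alternatives of 0.00356 to 0.104.

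The 13 protein-coding genes of the mitochondrial genome went the other way. Of these, 11 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -2.05 (camera adjusted p = 3.99e-05; adjusted p = 0.385 with an estimated correlation). COX1 had 5915 ± 4055 CPM in Asrij low and 902 ± 76.0 CPM in Asrij high (log2 -2.71 ± 0.43, adjusted p = 0.00146), and COX2 (-2.29), COX3 (-2.12) and ATP6 (-2.13) fell, the last sharing counts with a nuclear copy. ND3 (-0.71, adjusted p = 0.23) and ND6 (-1.53, adjusted p = 0.0676) did not pass the test, though ND6 did under library totals (adjusted p = 0.0347), upper quartile factors (0.0309) and limma-voom with and without sample quality weights (0.0443 and 0.049), and without Asrij low replicate 2 (0.0193; range over alternatives 0.0132 to 0.279). These genes took 1.11%, 1.04% and 2.64% of counts in Asrij low replicates 1 to 3 and 0.238% to 0.306% in Asrij high. Ribosomal RNA loci, which the protocol's depletion targets, took 4.58% to 5.63% of counts in Asrij low and 1.49% to 3.97% in Asrij high. Of 56 tested ribosomal RNA genes, 45 fell and 1 rose. The signal recognition particle RNA took 1.07%, 2.06% and 4.91% in Asrij low replicates 1 to 3 and 0.54% to 1% in Asrij high. Without Asrij low replicate 3 the median was -1.46, COX1 was at -2.01, COX2 at -1.67 and ND6 at -0.63, and with Asrij high replicate 2 left out as well the median was -1.30 and ND3 was at 0.13.

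Other metabolic lists were mixed. Oxidative stress defence genes had 19 rises and 4 falls among 30 (20 and 6 adjusted over the list alone; median 1.03, camera adjusted p = 0.00215; adjusted p = 0.33 with an estimated correlation), with the mitochondrial peroxiredoxin gene Prdx3 (1.90) and the superoxide dismutase gene Sod1 (1.52) higher and the heme oxygenase gene Hmox1 lower (-3.37 ± 0.46, adjusted p = 9.79e-04). Cat (-0.63), Sod3 (-4.41) and Gpx3 (-2.23) fell too, but none of these was past the threshold without Asrij low replicate 3 (adjusted p = 0.0566, 0.0733 and 0.191), Asrij high replicate 2 (0.0508, 0.0957 and 0.129) or Asrij high replicate 3 (0.0734, 0.0505 and 0.16). Neither were Sod3 and Gpx3 without Asrij high replicate 1 (0.096 and 0.197), nor Cat and Gpx3 without Asrij low replicate 1 (0.0599 and 0.075). Over alternatives the 3 genes ran from 0.00445 to 0.0734, from 0.00109 to 0.14 and from 0.00222 to 0.221. Without Asrij low replicate 3 Gpx3 was at -1.19 and Sod3 at -3.70, and without Asrij high replicate 3 Sod3 was at -5.70. Glycolysis genes were not called as a list (9 rises and 8 falls of 25, median 0.20, camera adjusted p = 0.733), and their median was below 0 under library totals (-0.07) and upper quartile factors (-0.06). Hypoxia response genes (6 and 7 of 22, median -0.19, camera adjusted p = 0.602) and fatty acid oxidation genes (9 and 2 of 25, median 0.35, adjusted p = 0.226) were not called either. Nor were cholesterol synthesis genes (1 and 3 of 22, median -0.27, adjusted p = 0.658) or autophagy and lysosome genes (6 and 6 of 37, median -0.02, mean 0.00, adjusted p = 0.825), for which camera pointed down and fry up. Adjusted over the list alone, rises and falls in these 5 lists were 9 and 8, 6 and 7, 10 and 2, 1 and 1, and 6 and 5. Within them, the lactate transporter gene Slc16a1 (2.18) and Ldha (1.13) rose, and the glucose transporter gene Slc2a1 (-1.70) and Aldoc (-2.74) fell. Pparg (-3.85, or -2.92 without Asrij low replicate 3 and -4.18 to -2.52 over alternatives) fell in the fatty acid list, and in the cholesterol list Pmvk rose (1.19) and Srebf2 fell (-1.15). Insig1 (-0.79) and Stard4 (-0.74, adjusted p = 0.0499) fell too, but both were past the threshold only without Asrij low replicate 3 among fits with 1 library left out. Without Asrij low replicates 1 and 2 they were at adjusted p = 0.0785 and 0.162 (Insig1) and 0.0735 and 0.182 (Stard4), and without Asrij high replicates 1 to 3 at 0.0685, 0.0593 and 0.0941 and at 0.104, 0.0521 and 0.0871. Their ranges over alternatives were 0.0101 to 0.162 and 0.0115 to 0.182, and their log2 fold changes were -0.39 and -0.34 without Asrij low replicate 2.

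Proteasome and ribosome biogenesis genes rose. In the proteasome list 32 of 33 subunit genes rose and 0 fell (33 and 0 adjusted over the list alone; median 1.43, camera adjusted p = 2.29e-11), and in the ribosome biogenesis and MYC target list 38 of 40 rose and 1 fell, both also adjusted over the list alone (median 1.47, camera adjusted p = 2.10e-12). Both had an adjusted p = 0.33 with an estimated correlation. Psmd13 rose by 1.56 ± 0.17, Cad, which catalyses the first steps of pyrimidine synthesis, by 1.85 ± 0.15 and the spermidine synthase gene Srm by 1.69 ± 0.17. The member that fell was Mycn (-2.19, adjusted p = 0.0161), which was not past the threshold without Asrij high replicate 3 (0.0674, range over alternatives 3.75e-06 to 0.107) or without a count filter (0.107). It was at -3.07 without Asrij high replicate 2 and ran from -1.88 to -3.33 over alternatives. Cytosolic ribosomal protein genes had 45 rises and 0 falls among 71 (51 and 0 adjusted over the list alone; median 0.81, camera adjusted p = 5.28e-09; adjusted p = 0.445 with an estimated correlation), and many have processed pseudogenes that can share reads. Unfolded protein and heat shock genes had 16 rises and 1 fall among 29 (18 and 1 adjusted over the list alone; median 0.79, camera adjusted p = 1.06e-04; adjusted p = 0.334 with an estimated correlation). The asparagine synthetase gene Asns rose from 8.98 ± 1.08 to 139 ± 30.2 CPM (log2 3.95 ± 0.22, adjusted p = 1.09e-04) and the chaperone gene Hspa5 by 1.56, while Trib3 fell (-3.67).

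JAK-STAT, NF-kB, interferon, TGF-beta and BMP, and immediate early gene lists were lower in Asrij high. JAK-STAT targets and components had 17 falls and 1 rise among 30 (18 and 1 adjusted over the list alone; median -0.97, camera adjusted p = 1.02e-04; adjusted p = 0.33 with an estimated correlation). NF-kB and inflammatory genes had 21 falls and 1 rise among 30 (22 and 2 adjusted over the list alone, median -1.35, camera adjusted p = 1.15e-05; adjusted p = 0.33 with an estimated correlation). Interferon response genes had 23 falls and 0 rises among 43 (28 and 1 adjusted over the list alone, median -1.07, camera adjusted p = 1.29e-07; adjusted p = 0.33 with an estimated correlation). TGF-beta and BMP pathway genes had 18 falls and 0 rises among 29 (20 and 0 adjusted over the list alone, median -1.06, camera adjusted p = 1.69e-06; adjusted p = 0.33 with an estimated correlation). Immediate early and dissociation genes had 19 falls and 0 rises among 27 (21 and 0 adjusted over the list alone, median -1.76, camera adjusted p = 1.29e-07; adjusted p = 0.33 with an estimated correlation). Some marker lists of other cell types were lower along with these lists, with medians of -3.34 for B cell, -2.50 for T and NK cell, -3.60 for mesenchymal and -1.53 for monocyte, macrophage and dendritic markers. Stat3 itself was at 225 ± 19.5 CPM in Asrij low and 81.2 ± 23.6 CPM in Asrij high (log2 -1.47 ± 0.22, adjusted p = 0.00117), and the feedback inhibitor gene Socs3 fell by 2.99. Nlrp3 (-3.83), Irf1 (-1.54), Oasl2 (-2.11), Smad6 (-3.50), Zfp36 (-1.99) and Dusp1 (-2.09) fell, while Tnfaip2 in the NF-kB list rose (1.67). Ptpn11 rose in the JAK-STAT list (0.56, adjusted p = 0.0143) and lost its call under library totals (0.149, range over alternatives 0.00207 to 0.149), upper quartile factors (0.102) or without Asrij low replicate 1 or Asrij high replicate 1 or 3 (0.0518, 0.057 and 0.0646).

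Wnt pathway genes had 8 falls and 2 rises among 29 (6 and 2 adjusted over the list alone; median -0.62, camera adjusted p = 0.0164; adjusted p = 0.33 with an estimated correlation), with Tcf7l2 (-2.36) lower and Fzd7 (1.17) and Rnf43 (2.48) higher. Whether these falls, and those in the Notch list, share a source with the lower lymphoid and mesenchymal markers was not tested. Notch pathway genes had 12 falls and 5 rises among 31 (14 and 5 adjusted over the list alone) and were just short of a list call (median -0.45, camera adjusted p = 0.0554), with Notch1 (-1.81) and Maml2 (-2.42) lower and the protease gene Adam17 (0.95) higher. Psenen (0.76), Dtx4 (1.93) and Rfng (0.59) rose too, but were not past the threshold without Asrij high replicate 1 (adjusted p = 0.076, 0.0845 and 0.175). Dtx4 was not without Asrij low replicate 1 or Asrij high replicate 2 either (0.0563 and 0.0543), nor Rfng without Asrij low replicate 2 or 3 or Asrij high replicate 2 or 3 (0.0722, 0.0774, 0.0637 and 0.131). Their ranges over alternatives were 0.00283 to 0.076, 7.49e-04 to 0.0942 and 0.0332 to 0.288. The PI3K-AKT-mTOR list (6 rises and 8 falls of 31, also adjusted over the list alone, camera adjusted p = 0.825) was not called. Its median (0.11) and mean (-0.01) differed in sign, camera pointed down and fry up, and the median was -0.16 under library totals and upper quartile factors.

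Erythroid markers went both ways. Of 24, 12 rose and 5 fell (13 and 6 adjusted over the list alone; median 1.54, camera adjusted p = 0.0125; adjusted p = 0.629 with an estimated correlation), and the list was not called without Asrij low replicate 2 (adjusted p = 0.108, range over alternatives 4.07e-05 to 0.629). The carbonic anhydrase gene Car1 went from 75.4 ± 7.67 to 1250 ± 211 CPM (log2 4.05 ± 0.21, adjusted p = 1.09e-04), the erythropoietin receptor gene Epor from 34.4 ± 2.08 to 153 ± 28.5 CPM (log2 2.15 ± 0.18, adjusted p = 1.98e-04), and Klf1 rose by 2.01. The falls were those of the globin genes Hba-a1 (-3.05, adjusted p = 0.0126), Hbb-bs (-2.90, adjusted p = 0.0101) and of Alas2 (-3.08, adjusted p = 0.0112), the first enzyme of haem synthesis in red cells, with the near-identical globin copies Hba-a2 (-3.06) and Hbb-bt (-2.85). The first 3 falls were not past the threshold without Asrij high replicate 1 (adjusted p = 0.129, 0.112 and 0.134), 2 (0.0737, 0.0604 and 0.0971) or 3 (0.0652, 0.0571 and 0.0611). Neither were Hba-a2 (0.126, 0.0711 and 0.0618) and Hbb-bt (0.129, 0.0741 and 0.0655) without the same libraries. Over alternatives the adjusted p of Hba-a1, Hbb-bs and Alas2 ran from 6.94e-04 to 0.129, from 5.45e-04 to 0.112 and from 7.33e-04 to 0.134. Without Asrij low replicate 3, Hba-a1 was at -1.98, Hba-a2 at -1.997, Hbb-bs at -1.95, Hbb-bt at -1.88 and Alas2 at -1.999. Globin genes took 3.11%, 1.17% and 8.29% of counts in Asrij low replicates 1 to 3 and 0.289% to 0.558% in Asrij high.

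Granulocyte markers also went both ways and were not called as a list (6 rises and 6 falls of 26, also adjusted over the list alone, median 0.33, camera adjusted p = 0.832). The granule protease gene Ctsg rose, at 10.6 ± 6.31 CPM in Asrij low and 228 ± 102 CPM in Asrij high (log2 4.42 ± 0.60, adjusted p = 0.00146) and the myeloperoxidase gene Mpo rose by 4.16 on the log2 scale, a call that was lost without Asrij high replicate 1 (adjusted p = 0.0536, range over alternatives 1.75e-14 to 0.0536). Among the falls were those of Retnlg (-3.47 ± 0.52, adjusted p = 0.00141), Mmp8 (-3.04) and Mmp9 (-3.21), the last of which lost its call without Asrij high replicate 1 or 2 (at -3.32 and -2.99, adjusted p = 0.0803 and 0.0534) or a count filter (0.06; range over alternatives 1.82e-10 to 0.0803). S100a8 (1.06, adjusted p = 0.253) and S100a9 (0.54, adjusted p = 0.54), which are abundant in neutrophils, did not pass the test, and without Asrij high replicate 3 they were at 0.13 and -0.22. The list of multipotent progenitor and lineage priming genes had 7 rises and 10 falls among 23, also adjusted over the list alone, and was not called (camera adjusted p = 0.484), and its median (-0.61) and mean (0.11) differed in sign. Ms4a3, a granulocyte-monocyte progenitor gene, rose by 3.89 ± 0.34 and Cd27 fell by 2.09.

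**Figure D3:**
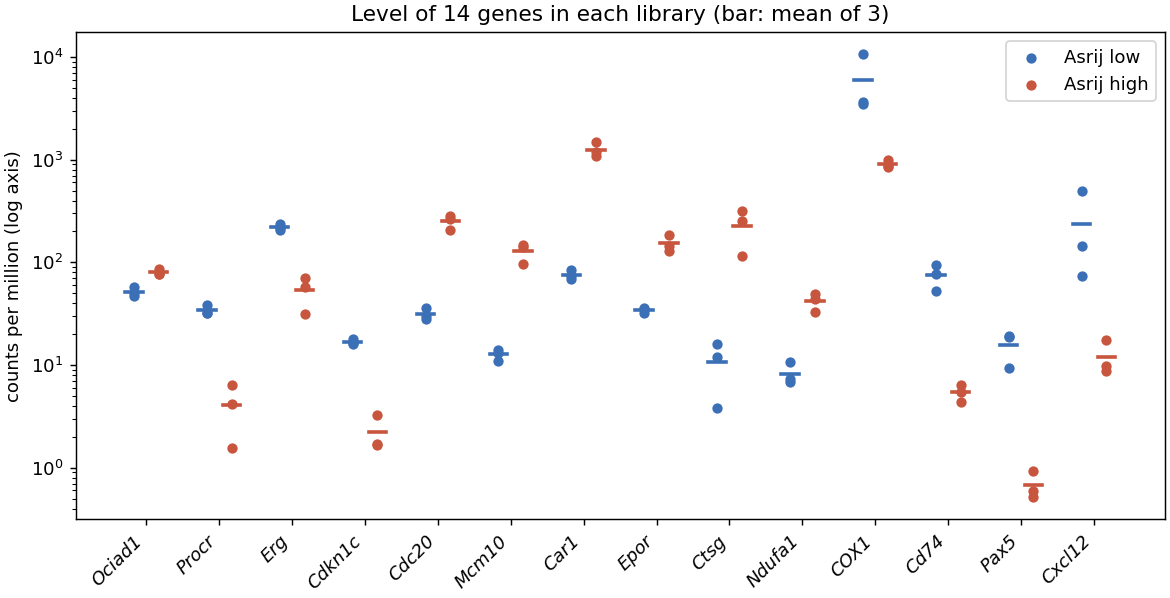
Level of selected genes in each library, in CPM on a log axis, with a point per library and a bar at the mean of 3 libraries. Procr fell from 34.3 to 4.06 CPM and Car1 rose from 75.4 to 1250 CPM, and the 3 points of a group do not overlap those of the other in any gene drawn.

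Markers of lymphoid, stromal and endothelial cells were higher in Asrij low. B cell markers fell in Asrij high in 15 of 22 cases and rose in 0 (17 and 0 adjusted over the list alone; median -3.34, camera adjusted p = 1.23e-08), and mesenchymal and bone lineage markers in 17 of 22 and rose in 0 (18 and 0 adjusted over the list alone; median -3.60, camera adjusted p = 1.49e-07), each at an adjusted p = 0.33 with an estimated correlation. T and NK cell markers had 9 falls and 0 rises among 20 (10 and 0 adjusted over the list alone; median -2.50, camera adjusted p = 1.74e-05; adjusted p = 0.33 with an estimated correlation). Endothelial markers had 10 falls and 0 rises among 22, also adjusted over the list alone (median -2.14, camera adjusted p = 0.00124; adjusted p = 0.372 with an estimated correlation). Erg and Pecam1 (-1.77) in that list are also expressed by HSCs. Of its 24 members, 7 also stand in another list, and Erg and others are HSC identity members, whose median was -1.97. The fall of this list therefore need not come from endothelial cells. Pax5, a B lineage transcription factor gene, was at 15.7 ± 5.50 CPM in Asrij low and 0.679 ± 0.217 CPM in Asrij high (log2 -4.52 ± 0.43, adjusted p = 2.30e-04), and Cd4 fell by 2.55. Cxcl12, a chemokine of marrow stroma, was at 237 ± 224 CPM against 12.1 ± 4.75 CPM (log2 -4.30 ± 0.73, adjusted p = 0.00331). Its level was 493 CPM in Asrij low replicate 3 and 145 and 74.3 CPM in replicates 1 and 2, and its call was lost without Asrij high replicate 1 (adjusted p = 0.0758, range over alternatives 4.52e-06 to 0.0758). Without Asrij low replicate 3, Cxcl12 was at -3.21 and the mesenchymal median at -2.68, and without Asrij high replicate 3 that median was -4.36. The B cell median was -2.30 in limma-voom (-2.73 with sample quality weights), -4.20 with the stricter count filter and -2.51 with Asrij low replicate 3 and Asrij high replicate 2 both left out, and the mesenchymal median was -2.84 without a count filter and -2.90 with both left out.

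Monocyte, macrophage and dendritic markers and eosinophil, basophil and mast cell markers were also lower in Asrij high as lists. Monocyte, macrophage and dendritic markers had 12 falls and 2 rises among 25 (17 and 2 adjusted over the list alone; median -1.53, camera adjusted p = 3.28e-04; adjusted p = 0.426 with an estimated correlation), and the complement gene C1qa (-3.60, or -3.02 without Asrij low replicate 3) and the invariant chain gene Cd74 (-3.79) fell. Zbtb46 (3.29, or 3.89 without Asrij low replicate 3) and Ly6c2 (2.32) rose, the latter not past the threshold without Asrij high replicate 1, 2 or 3 (adjusted p = 0.111, 0.0671 and 0.0621; range over alternatives 2.03e-05 to 0.111). Eosinophil, basophil and mast cell markers had 11 falls and 1 rise among 18, also adjusted over the list alone (median -1.98, camera adjusted p = 0.00385; adjusted p = 0.33 with an estimated correlation), with Ear2 lower (-2.37) and the receptor gene Il1rl1 higher (1.73). Kit (-0.85), which HSCs also express, fell. Antigen presentation genes fell in 13 of 23 cases and rose in 0 (14 and 0 adjusted over the list alone; median -0.77, camera adjusted p = 7.05e-06; adjusted p = 0.383 with an estimated correlation), with H2-Aa lower (-3.45). Megakaryocyte and platelet markers had 3 falls and 1 rise among 25, also adjusted over the list alone (median -0.69, camera adjusted p = 0.0182; adjusted p = 0.551 with an estimated correlation). Gata1, which is shared with erythroid cells, rose by 1.63. That list was not called without Asrij low replicate 3 (adjusted p = 0.0617), Asrij high replicate 1 (0.0838) or Asrij high replicate 3 (0.0703), with a range over alternatives of 5.98e-04 to 0.551.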

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

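Thinning to the smallest library, leaving out Asrij low replicate 3 and Asrij high replicate 2 together, and leaving out libraries for the comparison of library correlations were chosen after seeing the data. The count of changed genes ran from 4930 (adjusted p under 0.01) to 11351 (limma-voom with sample quality weights, within 1.5 times) over 20 alternatives, and from 5481 (without Asrij high replicate 1) to 8935 with 1 library left out. With both libraries left out it was 8367, 7146 of them among the 8452. In no alternative was a called gene called in the opposite direction. The cause of the lower count without Asrij high replicate 1 was not tested. The share of higher calls was 40.2% under library totals and 39.9% under upper quartile factors.

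Ociad1 kept its direction, with log2 0.359 (library totals) and 0.362 (upper quartile), 0.531 to 0.760 with 1 library left out, and 0.636 past 0.05 but not 0.01. The replicate numbers are not stated to pair samples, and deviations of equal numbers correlated by 0.01, 0.05 and 0.22, and Asrij low replicates 1 and 2 did not correlate best with their own number. With the replicate block 8088 genes were called, 7587 of them shared, and 34 lists.

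Of 34 called lists, 29 kept their call in all alternatives but an estimated correlation and the 0.01 threshold. With an estimated correlation 0 lists were called, with adjusted p of 0.33 (most lists), 0.334, 0.349, 0.372, 0.383, 0.385, 0.426, 0.445, 0.484, 0.551 and 0.629. At an unadjusted p under 0.05 that test had 3 lists, and fry called 36. The loss also met lists whose estimated correlation was below the preset 0.01 (homing 0.0084, eosinophil, basophil and mast cell -0.04). These had the same adjusted p of 0.33 as the G2/M list, whose estimated correlation was 0.64. The adjustment gives many lists this same value, so equal values can hide different unadjusted p-values. Some lists with a high estimated correlation had larger values, as cytosolic ribosomal proteins (0.68, adjusted p = 0.445) and mitochondrially encoded genes (0.91, adjusted p = 0.385). How far the loss followed a list's correlation is therefore not settled. This form of camera also has few degrees of freedom here. The loss does not by itself show that correlation between genes undoes these calls. Homing and niche receptors had 0.0512 (upper quartile), 0.0599 (thinned), 0.192 (both libraries left out), 0.0425 (not past 0.01) and 0.0317 to 0.102 with 1 library left out. Megakaryocyte markers had 0.0678 (DESeq2), 0.173 (fry), 0.0182 (not past 0.01) and 5.98e-04 to 0.0838, the ageing list 0.15 (fry) and 0.00111 to 0.053, Wnt 0.0546 (stricter filter) and 0.0164 (not past 0.01), and erythroid markers 0.0125 (not past 0.01) and 0.00103 to 0.108. The Notch list gained a call under library totals (0.0391), upper quartile (0.0384), DESeq2 (0.0282), limma-voom (0.037, with weights 0.0424), no filter (0.0316), thinning (0.0403), a threshold of 0.1 (0.0554) and fry (0.00718). Fry also called p53 targets (0.00627), apoptosis regulators (0.00689) and sex chromosome transcripts (0.0461). Uncalled lists changed direction without a call: PI3K (0.987 without a filter, 0.827 with fry, 0.999 and 0.929 without Asrij low replicate 1 or 2; 0.638 to 0.999 with 1 library left out), autophagy (0.859 without a filter, 0.826 with fry, 0.977 with both left out, 0.792 without Asrij high replicate 2; 0.729 to 0.999), chromatin regulators (0.868 with fry, 0.929 without Asrij low replicate 2; 0.638 to 0.929), cholesterol (0.544 without Asrij low replicate 2; 0.145 to 0.883) and granulocyte markers (0.516 and 0.883 without Asrij low replicate 2 or Asrij high replicate 3; 0.339 to 0.883). Without mitochondrially encoded genes that list had no value.

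Of 251 named genes, 246 were past the threshold. Ociad1 and 44 others lost the call somewhere, and 2, neither past it, changed sign: S100a9 (-0.220 without Asrij high replicate 3; 1 library left out gave -0.220 to 0.987) and ND3 (0.134 with both left out). Another 2 gained a call somewhere, S100a8 with the replicate block alone (log2 0.923, edgeR adjusted p = 0.00592, range over alternatives 0.00592 to 0.911) and ND6 with it (0.0132, range 0.0132 to 0.279) and in 6 others. Of 244 named genes present in both groups, 51 moved by over 1.5 times in some alternative, 45 of them with both libraries left out, 32 without Asrij low replicate 3, 20 in limma-voom with sample quality weights and 7 without weights. Within-group correlation exceeded that between groups by 0.071, by 0.668 over the 500 most variable genes and by 0.055 to 0.081 with 1 library left out. Depth limited low genes in the Asrij low libraries most, and the cause of other changes was not tested.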

Other observations

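The tests of the order of libraries within Asrij high, of the stem cell share, of ratios between Asrij low libraries and of Asrij low replicate 3, and the thinning of libraries, were chosen after the results were seen. Further lists fixed before the data were examined were not called with camera and held members that went both ways. Among 35 chromatin regulators of stem cells, 9 rose and 7 fell in Asrij high (9 and 9 adjusted over the list alone; camera adjusted p = 0.75). Their median (-0.09) and mean (0.02) differed in sign, and camera pointed down and fry up. The histone methyltransferase gene Ezh2 rose from 62.8 ± 8.80 to 243 ± 48.2 CPM (log2 1.95 ± 0.20, edgeR adjusted p = 2.98e-04), with Suz12 (1.35) and the maintenance DNA methyltransferase gene Dnmt1 (1.38), whereas Tet1 fell (-1.36). Among 30 apoptosis regulators, 9 rose and 6 fell (10 and 6 adjusted over the list alone; median 0.01, but -0.03, -0.26 and -0.25 under RLE, library totals and upper quartile factors; camera adjusted p = 0.645). Cycs, which encodes cytochrome c, rose by 2.42. The lncRNA genes Neat1 (-1.75) and Meg3 (-3.13) fell and Snhg12 rose (1.34), in a list of non-polyadenylated and nuclear RNA with 1 rise and 2 falls among 17, also adjusted over the list alone (median -0.60, camera adjusted p = 0.133). Of 10 sex chromosome transcripts, 2 rose and 0 fell, also adjusted over the list alone (median 0.25, but -0.03 under library totals and upper quartile factors; camera adjusted p = 0.317), namely the X-linked Eif2s3x (1.53) and Ddx3x (1.17).

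The first of 3 patterns, seen in the data first and so explained only by hypotheses, is that HSC identity genes were lower and cell cycle genes higher in Asrij high. With all libraries thinned to the smallest total, the HSC identity median was -2.09 and the G2/M median 2.73. Random thinning leaves the expected fold change of a gene unchanged, so this outcome was nearly fixed in advance and does not decide on depth. A bias of gene length or GC content is argued against as the whole cause, since after its trend was removed the medians were -1.73 and 3.02. A larger share of committed progenitors in the Asrij high sort stays open: of the 29 HSC identity members that fell, 27 (93.1%) were highest within Asrij high in replicate 2, in which 11 of the 12 risen erythroid markers were lowest, but that library also lay nearest to Asrij low on the first principal component (70.2, against 137 and 112), so the order decides nothing. A change of state within the sorted stem cells stays open too and was not tested.

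The second pattern is that B cell, T and NK cell and mesenchymal markers were higher in Asrij low. Of the 25, 28 and 28 members of these lists, 1, 1 and 2 also stand in another list. After thinning, the B cell and mesenchymal medians were -3.43 and -3.77, which for the same reason does not decide on depth. RNA of a single common source carried over into these libraries would change both lists in the same ratio. Called B cell and mesenchymal members changed in different ratios in 3 of 3 pairs of Asrij low libraries. The ratios were log2 0.65 and 2.49 from replicate 2 to replicate 3, a difference of 1.83 ± 0.60 SE. From replicate 1 the differences were -0.88 ± 0.42 SE to replicate 2 and 0.62 ± 0.21 SE to replicate 3. This weighs only weakly against a common source, since these SE treat genes as independent, each ratio rests on single libraries and the pairs share libraries. A lower share of stem cells there stays open although 29 of 35 HSC identity members were higher there, since the called markers had median levels of 8.58, 8.43 and 9.05 CPM in Asrij low against 50.6 CPM for HSC identity members, and a small share of other cells would leave these near their level; several sources of carried-over RNA or cells, which a stem cell gate should exclude, and expression in the sorted cells themselves were not tested, nor was whether the falls of the JAK-STAT, NF-kB, interferon and TGF-beta lists share a source with these markers. Among the most abundant markers, Ighm (log2 -1.59) was at 32.7 ± 21.2 CPM in Asrij low and 10.9 ± 2.51 CPM in Asrij high, Igkc (-4.64) at 30.6 ± 39.1 and 1.23 ± 0.895 CPM, Lat (-1.65) at 60.4 ± 5.36 and 19.3 ± 15.5 CPM and Igfbp5 (-4.11) at 129.6 ± 143 and 7.48 ± 3.76 CPM. All 4 calls were lost without Asrij high replicate 1 (edgeR adjusted p = 0.0687, 0.112, 0.0667 and 0.122), those of Igkc and Igfbp5 also without replicate 2 (0.0966 and 0.0793), those of Ighm, Igkc and Lat without replicate 3 (0.0636, 0.0875 and 0.0639), and that of Lat without Asrij low replicate 1 or 2 (0.054 and 0.0543), with ranges over alternatives of 4.17e-04 to 0.0687, 4.69e-04 to 0.115, 9.51e-05 to 0.131 and 7.85e-05 to 0.122, and without Asrij low replicate 3 Ighm was at -0.96, Igkc at -2.71 and Igfbp5 at -2.68, without Asrij high replicate 1 Igkc at -5.36 and without replicate 2 Lat at -2.51.

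The third pattern is that mitochondrially encoded genes were lower while nuclear subunits of the same complexes were higher in Asrij high. Under the 3 other scalings the encoded median was at most -2.11 and the complex I median at least 1.13. RLE, library totals and upper quartile factors moved log2 fold changes by a median of only -0.051, -0.268 and -0.271. This outcome was therefore nearly fixed in advance and does not decide on scalings further away. A factor per library shifts both lists alike, so no such scaling makes the gap between them. Length and GC content are argued against, with medians of -2.38 and 1.30 after correction. Asrij low replicate 3, which had the highest share of these counts, was not the whole cause: without it the median was -1.46 and 11 of 13 members still fell. RNA quality or ribosomal RNA depletion that differed between the sorts (ribosomal RNA loci took 4.58% to 5.63% of counts in Asrij low and 1.49% to 3.97% in Asrij high), mitochondrial RNA per cell and the mix of cells stay open and were not tested.

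With edgeR the real split of the 6 libraries, 1 of 10 splits into 3 and 3, gave 8452 changed genes, and the highest of the others gave 0 (up to 516 genes at an unadjusted p under 0.05, against 10455 in the real split; no other tool was run on the splits). With 10 splits the share cannot fall below 0.05. Every other split holds libraries of both groups on each side, so the group difference adds to the spread within sides and lowers the calls. The contrast with 0 is therefore not one with a split free of a group difference.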
